A study of Arabidopsis thaliana with 30 samples.

How the data were processed

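RNA was sequenced from leaves at bolting of Arabidopsis thaliana Col-0, with total RNA named as the molecule. Per the submitters' processing notes, the authors trimmed paired reads of 150 bases with Trim Galore 0.6.6 and cutadapt 2.8 and aligned them to TAIR10 with STAR 2.7.10a. The deposited files hold counts of reads per gene, 1 file per library. The counting tool, its strand setting, the library kit and the mutant alleles are not given in the sources used here. Each file lists 34262 gene identifiers and 5 totals that name no gene. Of the identifiers, 32548 are nuclear and all of these were found in the reference annotation (TAIR10.1 coordinates), 133 are plastid and 152 mitochondrial, and the plastid and mitochondrial genes are at 0 in every library.

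The 30 libraries fall into 10 groups of 3 and 4 sets, as the labels pair each mutant with a wild type. The share of entries assigned to no gene was 2.58% to 5.78% in the 12 h set with cue1 and hda6 and 48.5% to 49.4%, 48% to 48.6% and 49.1% to 49.6% in the sets with sal1, with cue1 and msh1, and with hda6 at 16 h. Between 22782 and 25158 genes had a count. The biological coefficient of variation was 0.149, 0.159, 0.131 and 0.0999 in the same order of sets. Of 24 same-numbered pairs of libraries across groups, 6 had a residual correlation over 0.1 (range -0.393 to 0.152). In the sets with sal1 and with hda6 at 16 h all such pairs were positive (0.0343 to 0.152), so pairing there is not excluded. Replicates were taken as independent, and a replicate block was run as an alternative.

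Each set was fitted by itself in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr with a minimum count of 10, libraries were scaled with TMM factors, and the quasi-likelihood F test gave p-values that were adjusted over all tested genes by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. The SE of a log2 fold change is its absolute value divided by the square root of F. Intervals and floors cover counting error only. For a group at 0 in all libraries, the fold is a lower bound from a floor of 3 counts over the group, and with 1 to 3 counts the ratio of counts is given with its 95% counting interval.

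Mutants were compared with the wild type of their set. The change of the cue1 and hda6 effects with day length was tested as an interaction over 4 groups. Wild types of the same day length were compared between sets, and day length was read from genes called in the same direction in all 4 pairs of sets. Overlaps of calls used Fisher's exact test, two-sided, per direction, and a log2 odds ratio pooled over both directions, against an expectation of the product of both counts over the genes tested in both. For pairs that share a wild type, 20 simulations of unchanged mutant groups gave the correlation that the shared libraries produce. Correlations of fold changes are across genes, which are not independent replicates.

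A total of 22 gene lists was written before the data were examined: nuclear photosynthesis, flavonoid, shikimate, phenylpropanoid and glucosinolate synthesis, salicylic acid, jasmonate, flowering time, circadian clock, heat shock, abscisic acid with cold and drought, reactive oxygen, mitochondrial dysfunction, phosphate, sulfate, nitrate, starch, DNA methylation with histone deacetylation, senescence, floral organs, stem secondary walls, and cell division. Lists were tested with camera (limma 3.58.1, inter-gene correlation 0.01, log2 CPM with a prior count of 2), adjusted over the lists of a comparison, again with a correlation estimated from the data, and with fry. Camera called 60 of 132 list tests and fry 46, with 36 shared. With an estimated correlation camera called 0 of them, with 9 at an unadjusted p under 0.05 and a lowest adjusted p of 0.243. Median, mean and test differed in sign in 23 lists, none of them called by camera, such as the clock list in cue1 at 12 h (median 0.0879, mean -0.389).

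Genes are named by a rule fixed before the data were examined. It takes the gene a mutant is named for, and the 6 highest and 6 lowest log2 fold changes among called nuclear genes with a mean of at least 5 CPM in 1 group and no overlap between the mutant and wild-type values, which chance gives for 10% of genes with 3 against 3 libraries. It adds the 2 members with the smallest adjusted p of each list with at least 3 called members, and FLC, MAF4 and MAF5 in the hda6 comparisons. For overlaps, interactions and day length it takes the 3 highest and 3 lowest. Other clock, photosynthesis and flowering members are named only as members of a counted list, after their values were seen. The part of a gene's exonic bases that exons on the other strand overlap is given where it exceeds 0.1, since such genes and near-identical paralogs cannot be counted with certainty.

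Recovery was tested on simulated data: of genes changed by a log2 of 1, 56% to 85.9% were recovered in the 6 mutant comparisons and 50.5% and 53% in the interactions, and of genes changed by a log2 of 2, 91.8% to 99% and 76.5% and 85.7%. False calls made up 3.05% to 9.64% of calls. Alternatives were DESeq2 1.42.0, RLE factors, scaling on nuclear genes, no filter, a filter of 1 CPM, an adjusted p under 0.01, a log2 of at least 1, a replicate block, all 30 libraries in one model, only the groups compared, and each library left out. Fits without 3474 genes with more than 0.25 of their bases overlapped on the other strand, and without 2 libraries that stood apart on the principal components (12 h wild-type replicate 2 and cue1 replicate 3), were added after the data were seen. Samples of the series outside the 10 groups were not analysed here.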

Results

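Transcripts were counted in leaves of bolting Arabidopsis thaliana plants of the Col-0 accession, taken from wild type and from 4 mutants. The mutants are cue1, affected in a phosphoenolpyruvate translocator of the plastid envelope, hda6, affected in a histone deacetylase, sal1, affected in a phosphatase that degrades the stress signal PAP, and msh1, affected in a MutS homologue that acts in plastids and mitochondria. Plants grew with 12 h or 16 h of light per day. The 30 libraries form 10 groups of 3 libraries, and the groups form 4 sets, each with its own wild type. The 12 h set with cue1 and hda6 held 32306939 to 33747006 gene counts per library. The 12 h set with sal1 held 15632452 to 21241223, the 16 h set with cue1 and msh1 17568323 to 22275044, and the 16 h set with hda6 14417942 to 22334743. Per the labels, the replicates are full siblings. All values below are means over n = 3 libraries with their SD, as CPM (counts scaled to a common library size), and log2 fold changes carry their standard error (SE).

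The genes for which the mutants are named came first, since they check the labels. CUE1 (AT5G33320, chromosome 5, 12588741 to 12591748, TAIR10.1, plus strand) stood at 126 ± 2.71 CPM in wild type and 10.9 ± 2.63 in cue1 at 12 h, and at 206 ± 7.46 and 15.4 ± 0.543 at 16 h. In the other 6 groups CUE1 lay between 86.3 ± 6.45 (hda6, 12 h) and 187 ± 15.5 CPM (libraries labelled sal1). HDA6 (AT5G63110, chromosome 5, 25315506 to 25318347, minus strand) fell at 16 h from 23.58 ± 2.64 to 15 ± 1 CPM in hda6 (log2 -0.65, SE 0.11, edgeR adjusted p = 0.00136). At 12 h HDA6 was at 27.3 ± 0.57 CPM in wild type and 24.1 ± 0.65 in hda6 (log2 -0.18, SE 0.06, edgeR adjusted p = 0.0427), a call that was lost without any 1 of the 6 libraries (adjusted p 0.0556 to 0.117) and with all 30 libraries in one model (0.0777). In the other 6 groups HDA6 lay between 24.3 ± 1.05 and 33.3 ± 1.75 CPM. SAL1 (AT5G63980, chromosome 5, 25610002 to 25611802, plus strand) was higher, not lower, in the libraries labelled sal1, at 245 ± 39.6 against 78.1 ± 9.29 CPM (log2 1.65, SE 0.14, edgeR adjusted p = 0.000112), and stood between 66.5 ± 4.58 and 119 ± 4.99 CPM in the remaining 8 groups. MSH1 (AT3G24320, chromosome 3, 8822924 to 8829728, minus strand) was likewise higher in the libraries labelled msh1, at 26.3 ± 2.03 against 9.83 ± 0.41 CPM (log2 1.42, SE 0.09, edgeR adjusted p = 1.91e-06), and stood between 9.16 ± 0.815 and 20.2 ± 3.67 CPM elsewhere. The last 2 transcripts were not lowered in the groups named for them. The alleles are not given in the sources used here, so these levels neither bear out nor contradict the labels. Directions drawn for these groups rest on the labels alone.

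**Figure D1:**
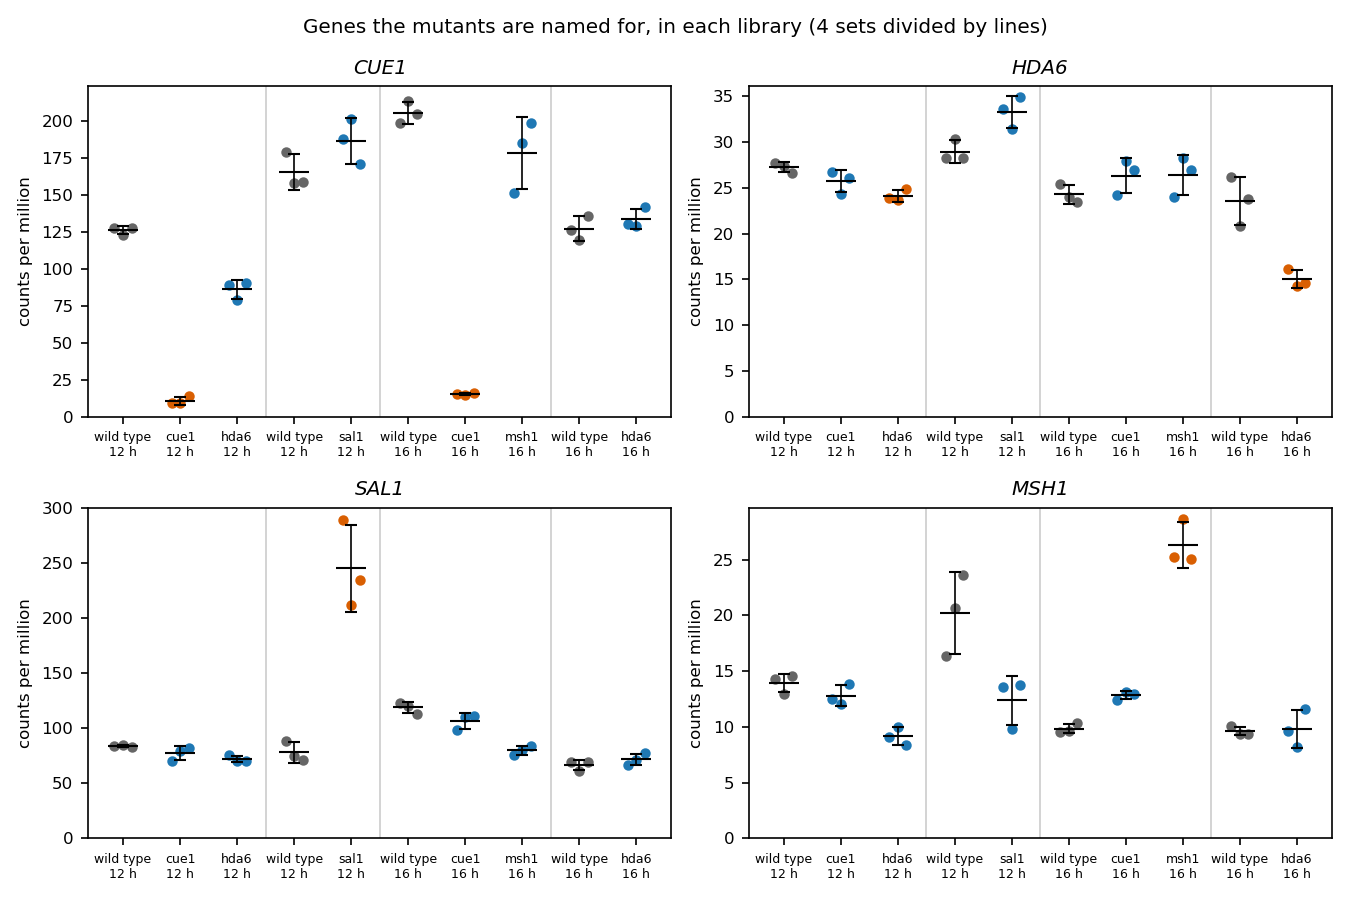
CPM of CUE1, HDA6, SAL1 and MSH1 in every library. Each point is 1 library, the bar is the group mean with its SD (n = 3), grey marks wild type, orange the mutant named for the gene and blue the others. CUE1 is at 10.9 and 15.4 CPM in the cue1 groups, whereas SAL1 and MSH1 are highest in the groups named for them (245 and 26.3 CPM).

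At 12 h, the morning clock genes LHY and CCA1 were lower in cue1 than in wild type: LHY at 0.835 ± 0.0798 against 6.72 ± 0.388 CPM (log2 -3.01, SE 0.17) and CCA1 at 6.38 ± 1.5 against 38.9 ± 6.92 CPM (log2 -2.61, SE 0.21). The circadian clock list had 7 of its 21 members higher, among them TOC1, ELF3, ELF4, LUX and FKF1, which are expressed late in the day, and 7 lower, among them PRR9, RVE1 and RVE8, with the other 7 not passing (8 and 8 adjusted over the list alone). AT3G04650, an oxidoreductase gene, rose from 5.46 ± 0.257 to 40.3 ± 3.59 CPM (log2 2.88, SE 0.09, edgeR adjusted p = 1.23e-06). The uncharacterised AT3G01345 rose by a log2 of 4.01 (SE 0.47), BT2, a BTB and TAZ domain protein, by 2.07 (SE 0.40), the histone demethylase gene JMJD5 by 1.48 (SE 0.21), RVE2 by 1.43 (SE 0.26) and SRG3 by 1.33 (SE 0.22). GBSS1, the granule-bound starch synthase, fell from 75.3 ± 18.6 to 18.23 ± 3.76 CPM, MRD1 had a log2 of -2.85 (SE 0.15) and COL2 of -2.21 (SE 0.31). MRD1, SRG3 and COL2 share a part of 0.898, 0.447 and 0.318 of their exonic bases with genes on the other strand and are uncertain.

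Of the jasmonate genes, 1 of 23 fell in cue1 at 12 h (10 adjusted over the list alone), and the list lay lower than other genes by camera (adjusted p = 4.96e-09, but adjusted p = 0.604 with an estimated correlation). The same held for sulfate assimilation (1 of 14 lower, 7 over the list alone, camera adjusted p = 6.65e-05, 0.604 as an adjusted p with an estimated correlation). In the phenylpropanoid list 4 of 17 members fell, 7 adjusted over the list alone, with C4H and PAL2 at log2 -0.45 (SE 0.07) and -0.59 (SE 0.10), and a camera adjusted p of 0.0012. Camera also called the abscisic acid and cold list (1 of 29 lower, 3 over the list alone, adjusted p = 0.000809) and the phosphate starvation list (1 of 18 higher, 3 over the list alone, adjusted p = 0.000809). Glucosinolate synthesis (camera adjusted p = 0.000973), flavonoid synthesis (0.000809), the reactive oxygen response (0.00817) and stem secondary walls (0.0126) were called lower as lists although 0 members passed edgeR. At an unadjusted p under 0.05 these lists held 9 of 27, 3 of 19, 3 of 18 and 0 of 12 members, and DESeq2 called 2, 2, 2 and 0. With an estimated correlation the adjusted p of these last 7 lists was 0.604 to 0.854. In the nuclear photosynthesis list 3 of 48 members rose and 1 fell (5 and 1 over the list alone, camera adjusted p = 0.16), and camera called the list higher without wild-type replicate 2 (adjusted p = 5.86e-05) or cue1 replicate 1 (0.0249). The 3 included LHCB4.3 (log2 0.67, SE 0.10) and the Rubisco small subunit gene RBCS2B (1888 ± 174 against 836 ± 155 CPM), whose family members are near-identical and uncertain.

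In all, edgeR's quasi-likelihood test called 381 of 20649 genes in cue1 at 12 h, 269 higher and 112 lower. DESeq2 called 1184. The count rested on single libraries, at 118 without wild-type replicate 1, 60 without wild-type replicate 3, and 32, 123 and 117 without cue1 replicates 1, 2 and 3. It also moved with a replicate block, with only the groups compared and with all 30 libraries in one model. Leaving out the 2 libraries that stood apart moved it as well, and these counts are given below. BT2 lost its call without any 1 of the 6 libraries (adjusted p 0.0576 to 0.128). JMJD5, RVE2, SRG3, COL2, RBCS2B, LHCB4.3, C4H and PAL2 each lost theirs without cue1 replicate 1 (adjusted p 0.0613 to 0.119), and all of these but RBCS2B also without wild-type replicate 3 (0.0623 to 0.112). SRG3, LHCB4.3 and C4H lost it without wild-type replicate 1 (0.0758, 0.0624 and 0.0597), and RVE2 and PAL2 without wild-type replicate 2 (0.0527 and 0.0636). RVE2, SRG3, LHCB4.3 and PAL2 lost it without cue1 replicate 2 (0.063, 0.0778, 0.0659 and 0.0845), and RVE2, COL2, LHCB4.3, C4H and PAL2 without cue1 replicate 3 (0.0695, 0.0575, 0.0695, 0.0521 and 0.0942). Of the lists, reactive oxygen genes lost the camera call without wild-type replicate 2 (adjusted p = 0.0656) or cue1 replicate 2 (0.11), and stem secondary walls without wild-type replicate 3 (0.0986) or cue1 replicate 1 (0.153). By fry 8 of these 9 camera calls were not made (adjusted p 0.185 to 0.531), the phenylpropanoid list excepted. Lists called lower by camera only with 1 library left out were cell division (0.0113 without wild-type replicate 2 and 0.0208 without cue1 replicate 2), salicylic acid (0.034 without wild-type replicate 3) and shikimate genes (0.0311, 0.0462 and 0.00285 without wild-type replicate 3 and cue1 replicates 1 and 3). With all 30 libraries in one model LHCB4.3 was not called (adjusted p = 0.106).

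At 16 h, cue1 again had lower LHY (3.43 ± 0.777 against 42.3 ± 8.58 CPM, log2 -3.61, SE 0.18) and CCA1 (11.8 ± 2.65 against 136 ± 6.54 CPM, log2 -3.52, SE 0.17). The evening gene FKF1, a light-sensing F-box protein of the flowering pathway, rose from 12.6 ± 1.57 to 89.9 ± 3.82 CPM (log2 2.83, SE 0.10, edgeR adjusted p = 5.86e-08), and LNK3, a transcriptional coactivator of the clock, had a log2 of -2.66 (SE 0.11). Of 21 clock genes 9 rose, 9 fell and 3 did not pass, also when adjusted over the list alone. MAF5, a floral repressor of the FLC family, stood at 0.761 ± 0.196 against 26.2 ± 3.85 CPM (log2 -5.12, SE 0.20). The other 16 h wild type, of the hda6 set, was at 1.04 ± 0.489 CPM, so this difference depends on the wild type used. AT1G07050 and AT4G33980 rose by log2 3.26 (SE 0.16) and 2.93 (SE 0.13), AT3G01345 by 4.70 (SE 0.75) and the noncoding AT3G06955 by 4.06 (SE 0.33). The efflux carrier gene AT2G04050 rose by 4.45 (SE 0.92) and AT2G18193 by 3.31 (SE 0.83), both with an SD above the mean in cue1. SEN1, a gene induced by darkness, had a log2 of -2.74 (SE 0.33) and MRD1 of -2.74 (SE 0.19). MRD1 is overlapped on the other strand in most of its exonic bases and is uncertain in this set too.

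Photosynthesis genes of the nucleus were lower in cue1 at 16 h: 13 of 48 fell and 35 did not pass, 42 fell when adjusted over the list alone, and camera gave an adjusted p of 3.09e-21 (adjusted p = 0.428 with an estimated correlation). The antenna gene LHCB2.2 went from 3132 ± 314 to 1539 ± 182 CPM (log2 -1.03, SE 0.16), and LHCB2.3 from 1628 ± 244 to 427 ± 142, but these genes are near-identical and a part of 0.406 of LHCB2.3 is overlapped on the other strand. Glucosinolate genes (4 of 27 lower, 14 over the list alone, camera adjusted p = 1.44e-07), phenylpropanoid genes (4 of 17, 9 over the list alone, 1.79e-05), stem secondary wall genes (2 of 12, 8 over the list alone, 3.19e-05) and nitrate assimilation genes (4 of 18, 7 over the list alone, 0.0032) were lower too, each at an adjusted p = 0.428 with an estimated correlation. In these lists PAL2 had a log2 of -0.91 (SE 0.11), PAL1 of -0.68 (SE 0.12), CYP79B3 of -0.63 (SE 0.12) and the nitrate transporter gene NRT1.1 of -0.81 (SE 0.14). Jasmonate genes were called as a list (1 of 22 lower, 1 over the list alone, camera adjusted p = 0.00146, adjusted p = 0.494 with an estimated correlation). Salicylic acid genes were higher (3 of 19, 10 over the list alone, camera adjusted p = 0.000212, adjusted p = 0.548 with an estimated correlation). The median log2 of this list fell from 1.06 to 0.274 without cue1 replicate 3, where camera still called it (adjusted p = 0.0135). WRKY54 stood at log2 1.32 (SE 0.24) and the pathogenesis gene PR1 at 1.89 (SE 0.48). In the mitochondrial dysfunction list 5 of 17 rose and 1 fell (7 and 1 over the list alone, camera adjusted p = 0.00317). The transporter gene ABCB4 stood at log2 1.21 (SE 0.18) and DTX1 at -0.72 (SE 0.11). The floral organ list had 2 of 10 members higher (5 over the list alone, camera adjusted p = 0.000448). Both had an adjusted p = 0.428 with an estimated correlation. By fry the glucosinolate, stem wall, jasmonate, salicylic acid and mitochondrial lists were not called (adjusted p = 0.0868, 0.062, 0.189, 0.189 and 0.0634).

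Further named genes changed in cue1 at 16 h. The starch synthase gene GBSS1 had a log2 of -1.24 (SE 0.18) and the starch branching enzyme gene SBE2.1 of 0.81 (SE 0.12), within a list with 3 members higher and 6 lower of 30. The stress genes DREB2A and ELIP1 had log2 values of 1.16 (SE 0.21) and -1.73 (SE 0.33), COR15B 1.35 (SE 0.28), HAB1 -0.58 (SE 0.12), GDH2 -0.58 (SE 0.10), APR2 -0.73 (SE 0.11) and SDI2 0.40 (SE 0.08), of which COR15B, APR2 and SDI2 are overlapped on the other strand to a part of 0.296, 0.464 and 0.274. The edgeR calls came to 1404 of 20785 genes, 694 higher and 710 lower, and to 728, 563 and 649 without wild-type replicates 1 and 2 and cue1 replicate 3. CYP79B2 (log2 -0.41, SE 0.11, edgeR adjusted p = 0.0398) lost its call without any 1 of the 6 libraries. AT2G04050, AT2G18193, PR1 and HAB1 lost theirs without wild-type replicate 1 (0.0649, 0.104, 0.116 and 0.0663) or 2 (0.0774, 0.122, 0.143 and 0.0574). AT2G18193 and PR1 also lost it without wild-type replicate 3 (0.0949 and 0.0532), PR1 without cue1 replicate 3 (0.0898), and COR15B and SDI2 without wild-type replicate 2 (adjusted p 0.0527 and 0.0697), SDI2 also without cue1 replicate 3 (0.0755). Without cue1 replicate 3 the log2 of PR1 was 0.95, without cue1 replicate 2 that of AT2G04050 was 2.796 and of AT2G18193 1.53, and without wild-type replicate 1 that of AT3G01345 was 5.54. With all 30 libraries in one model CYP79B3, CYP79B2, PR1 and GDH2 were not called (adjusted p = 0.0605, 0.129, 0.0914 and 0.137). Camera gained calls for 4 lists with 1 library left out. Without wild-type replicate 3 or cue1 replicate 3 these were shikimate genes, lower (0.024 and 0.0393), and cell division (0.00437 and 0.0135) and DNA methylation genes (0.039 and 0.0331), higher. DNA methylation genes were also called without cue1 replicate 2 (0.0206), and heat shock genes, lower, without cue1 replicate 3 (0.0142).

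The cue1 effect differed between day lengths for 168 of 21163 genes in edgeR's interaction test, 74 more positive and 94 more negative at 16 h. FKF1 was higher in cue1 by a log2 of 0.63 at 12 h and 2.83 at 16 h (difference 2.201, SE 0.15, adjusted p = 3.41e-05), AT1G07050 by 0.78 and 3.26 (difference 2.48, SE 0.15, adjusted p = 3.41e-05), and AT3G06955 differed by 3.84 (SE 0.56, adjusted p = 0.0105, and 0.0629 without 12 h wild-type replicate 1). MAF5 differed by -7.00 (SE 0.98, adjusted p = 0.00861), AT3G02370, a tRNA splicing endonuclease subunit gene, by -2.26 (SE 0.19) and AT4G33666 by -2.01 (SE 0.23), both overlapped on the other strand, to a part of 0.127 and 0.482. The MAF5 difference was -7.71 without 12 h wild-type replicate 3. At 12 h MAF5 was not called in cue1 (log2 1.876, edgeR adjusted p = 0.22). At 16 h the wild type of the cue1 set was at 26.2 ± 3.85 CPM and that of the hda6 set at 1.04 ± 0.489 CPM. Of the 21 clock genes, FKF1, PRR5 and PRR3 were more positive and LNK3 and RVE4 more negative at 16 h. Of the photosynthesis genes LHCB4.3 and RBCS2B were more negative at 16 h. The count of 168 became 56, 350 and 83 without 12 h wild-type replicates 1, 2 and 3, and 61, 72 and 64 without 12 h cue1 replicates 1, 2 and 3. It became 64, 47 and 67 without 16 h wild-type replicates 1, 2 and 3, and 92, 369 and 76 without 16 h cue1 replicates 1, 2 and 3, and DESeq2 called 925. Each day length was measured in its own set, so the day length and the set cannot be told apart here, and wild types of different sets at one day length also differed (7873 of 21044 genes between the 12 h sets and 4280 between the 16 h sets).

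**Figure D2:**
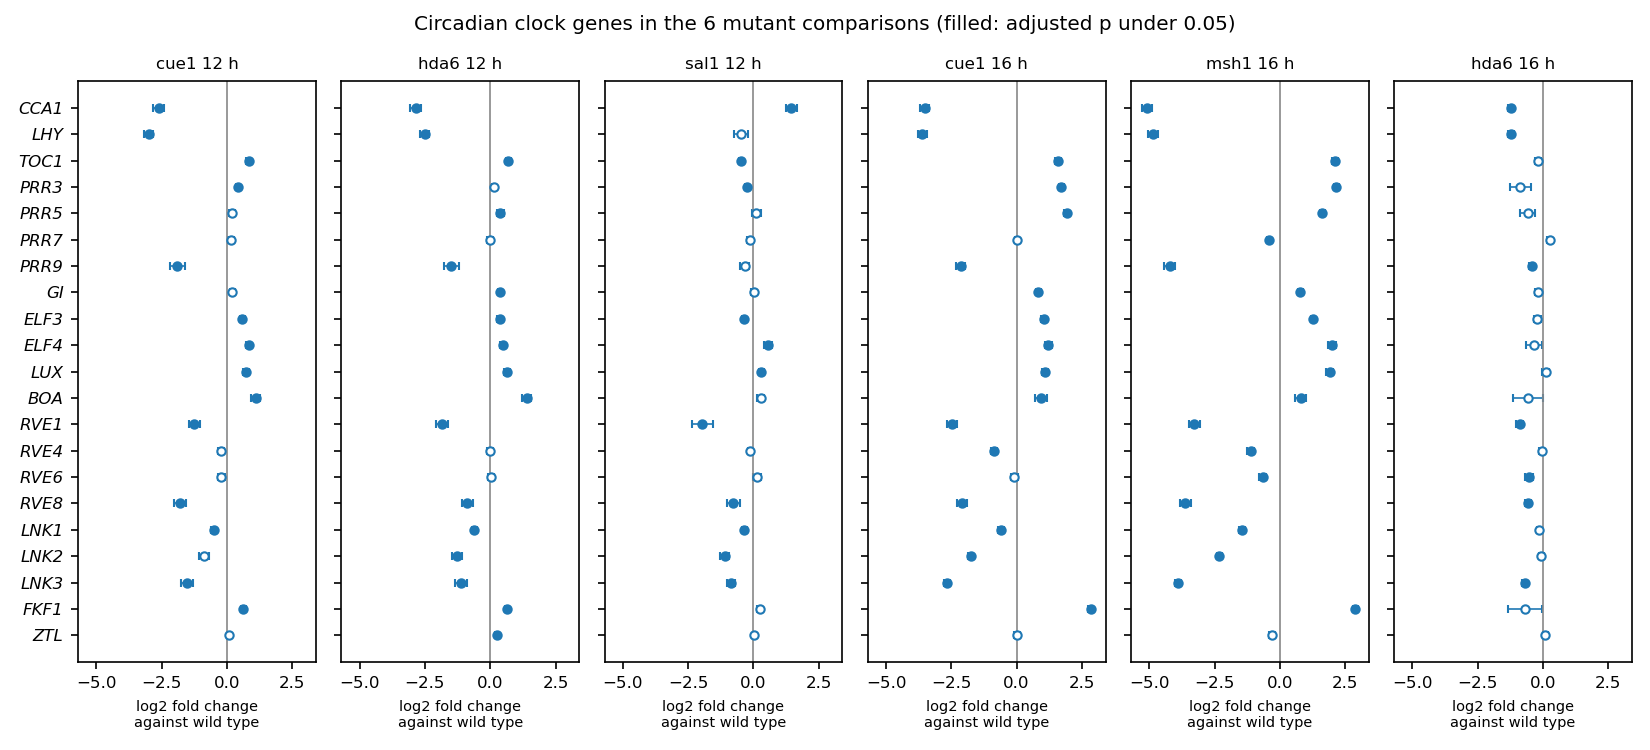
Log2 fold changes of 21 circadian clock genes against the wild type of the same set, with their SE, in 6 comparisons (n = 3 libraries per group). Filled points have an edgeR adjusted p under 0.05. CCA1 is at -2.61, -2.85, -3.52, -5.09 and -1.24 in cue1 12 h, hda6 12 h, cue1 16 h, the libraries labelled msh1 and hda6 16 h, and at 1.46 in the libraries labelled sal1.

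In hda6 at 12 h, genes with 0 counts in all 3 wild-type libraries were expressed. Against a floor of 3 counts over the group, the uncharacterised AT5G41660 (69.8 ± 10.8 CPM) was at least 2340-fold higher and AT4G16215 at least 2000-fold. AT3G44070, a glycosyl hydrolase gene overlapped on the other strand to a part of 0.156, was at least 1660-fold higher, AT4G07965 at least 860-fold, OFP9, a transcriptional repressor, at least 658-fold and AT3G60950 at least 638-fold. The floral repressors of the FLC family were higher, MAF4 at 7.81 ± 2.81 against 1.44 ± 0.721 CPM (log2 2.43, SE 0.49) and MAF5 at 35.4 ± 12.5 against 3.59 ± 2.9 CPM (log2 3.29, SE 0.71). FLC stood at 3.61 ± 2.37 against 0.9 ± 0.21 CPM (log2 2.00, SE 0.60, edgeR adjusted p = 0.0257), is overlapped to a part of 0.681 on the other strand, and kept its call without hda6 replicate 1 alone (adjusted p 0.00274 to 0.0997). Among the largest decreases were AT4G34220, a receptor kinase gene (1.68 ± 0.444 against 46.1 ± 8.57 CPM, log2 -4.77, SE 0.21), the expansin gene EXPA16 (log2 -4.23, SE 0.85), the ethylene synthesis gene ACO1 (-4.15, SE 0.89), LTP4 (-3.23, SE 0.88) and AT3G46490 (-3.19, SE 0.41). AT4G22475 fell to 1 count, a ratio of 0.001 (95% counting interval 2.54e-05 to 0.0056), is overlapped to a part of 0.815, and varied widely in wild type (9.7 ± 11.3 CPM). AT4G22475 and LTP4 lost their calls without hda6 replicate 2 (adjusted p = 0.0775 and 0.0632) or 3 (0.0598 and 0.0586). Without wild-type replicate 1 the log2 of ACO1 was -3.03, without hda6 replicate 1 that of LTP4 was -4.49, and without wild-type replicate 3 that of MAF5 was 3.99.

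In hda6 at 12 h, 14 of 18 members of the mitochondrial dysfunction list rose and 4 did not pass (15 rose over the list alone, camera adjusted p = 3.91e-06, adjusted p = 0.407 with an estimated correlation). The cytochrome P450 gene CYP81D8 stood at log2 1.66 (SE 0.12) and ABCB4 at 1.78 (SE 0.17). Of the reactive oxygen list 12 of 18 rose (12 over the list alone, camera adjusted p = 0.00163, adjusted p = 0.407 with an estimated correlation), including WRKY40 (log2 1.76, SE 0.22) and WRKY33 (1.48, SE 0.20). Senescence genes rose in 10 of 14 cases (11 over the list alone, camera adjusted p = 0.00163). The senescence regulator NAC092 stood at 35 ± 12 against 5.32 ± 0.768 CPM and WRKY6 at log2 1.75 (SE 0.19). Heat shock genes rose in 8 of 16 cases and fell in 1 (9 and 1 over the list alone, camera adjusted p = 0.00835). HSP70 stood at log2 0.97 (SE 0.13) and AT2G29500 at 1.71 (SE 0.19). Jasmonate genes rose in 9 of 23 (10 over the list alone, camera adjusted p = 0.00778), with JAZ1 at log2 1.09 (SE 0.18) and JAZ5 at 0.95 (SE 0.23). With an estimated correlation the adjusted p was 0.572, 0.572 and 0.606 for these 3 lists. Camera called no direction for abscisic acid, cold and drought genes (4 higher and 4 lower of 29, camera adjusted p = 0.801). Cell division markers fell in the same libraries in 15 of 17 cases, beside all of these rises. Over all 20649 tested genes edgeR called 4635 higher and 4040 lower, against which the list counts are to be read.

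Markers of cell division and young tissue fell in hda6 at 12 h in 15 of 17 cases (15 over the list alone, camera adjusted p = 8.67e-06, adjusted p = 0.572 with an estimated correlation). PCNA1 stood at 5.76 ± 1.18 against 12.8 ± 2.4 CPM and the replication gene MCM3 at log2 -0.80 (SE 0.11). These markers fell beside each of the following groups. Photosynthesis genes fell in 20 of 48 cases (20 over the list alone, camera adjusted p = 1.15e-05, adjusted p = 0.606 with an estimated correlation). LHCB1.1 stood at 640 ± 118 against 2339 ± 676 CPM. Glucosinolate genes fell in 21 of 27 cases and rose in 2 (21 and 2 over the list alone, camera adjusted p = 2.04e-05). IMD1 stood at log2 -1.61 (SE 0.21) and the regulator MYB51 at 1.67 (SE 0.14). Starch genes fell in 15 of 30 cases and rose in 2 (15 and 2 over the list alone, camera adjusted p = 0.000375). The translocator gene PPT2 stood at log2 -1.82 (SE 0.21) and the starch synthase gene SS1 at -0.78 (SE 0.09). DNA methylation and deacetylation genes fell in 13 of 32 cases and rose in 1 (14 and 1 over the list alone, camera adjusted p = 0.0021). The methyltransferase gene MET1 stood at log2 -1.04 (SE 0.14) and the demethylase gene ROS1 at -1.05 (SE 0.13). Sulfate assimilation genes fell in 6 of 14 cases (6 over the list alone, camera adjusted p = 0.03), with APK2 at log2 -1.58 (SE 0.13). With an estimated correlation the adjusted p of these last 4 lists was 0.572 to 0.606. The clock list had 9 members higher and 8 lower of 21, with LHY at log2 -2.51 (SE 0.17) and CCA1 at -2.85 (SE 0.21). Of 17 flowering time regulators 8 rose, among them FUL (log2 1.5, SE 0.27), and 3 fell (8 higher over the list alone, camera adjusted p = 0.174). Camera called no direction for salicylic acid genes (4 of 19 higher, among them CBP60G at log2 1.72, SE 0.31, camera adjusted p = 0.112) or phosphate starvation genes (6 higher and 1 lower of 18, with PHT1;5 at 2.49, SE 0.24, camera adjusted p = 0.157). The salicylic acid list was called higher without wild-type replicate 1 (camera adjusted p = 0.0217) or hda6 replicate 1 (0.0257), and the phosphate list without wild-type replicate 2 (0.03). By fry the photosynthesis and jasmonate lists were not called (adjusted p = 0.0789 for both), and the flowering (0.00766), phosphate (0.0417) and phenylpropanoid lists (0.00862) were. The sulfate assimilation call was lost without wild-type replicate 2 (camera adjusted p = 0.341). In total edgeR called 8675 of 20649 genes, 4635 higher and 4040 lower, 2778 of them at least 2-fold.

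At 16 h, hda6 again showed genes absent from the wild-type counts. The noncoding AT2G15555 stood at 108 ± 5.14 CPM with 0 counts in wild type, at least 2180-fold higher, AT5G15360 at least 1290-fold, AT4G08691 at least 1200-fold, AT4G29200 and AT3G44265, both related to galactosidases, at least 743-fold and 598-fold, and AT3G60950 at least 492-fold. MAF4 was at 9.23 ± 0.784 against 1.26 ± 0.7 CPM (log2 2.90, SE 0.27, edgeR adjusted p = 1.4e-06) and MAF5 at 7.6 ± 0.748 against 1.04 ± 0.489 (log2 2.90, SE 0.27). FLC had too few counts to be tested (0.929 ± 0.389 against 0.287 ± 0.247 CPM). The receptor kinase gene AT4G34220 had a log2 of -2.95 (SE 0.11), the ferric reductase gene FRO4 of -2.18 (SE 0.21), PORA, which acts in chlorophyll synthesis, of -2.04 (SE 0.10), AT3G27250 of -1.86 (SE 0.26), the ubiquitin ligase gene PUB19 of -1.83 (SE 0.35) and AT5G37940 of -1.72 (SE 0.37). AT5G37940 was not called by DESeq2 (adjusted p = 0.155) or with all 30 libraries in one model (0.267). The log2 of AT5G37940 was -2.86 without hda6 replicate 2 and that of PUB19 -2.41 without hda6 replicate 3.

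Abscisic acid, cold and drought genes were lower in hda6 at 16 h: 17 of 28 fell and 11 did not pass (20 fell over the list alone, camera adjusted p = 2.2e-09, adjusted p = 0.778 with an estimated correlation). COR15A stood at 37.2 ± 2.54 against 112 ± 38.9 CPM and RD29A at log2 -1.37 (SE 0.17). Salicylic acid genes fell in 8 of 18 cases (13 over the list alone, camera adjusted p = 2.85e-06), with WRKY70 at log2 -1.02 (SE 0.11) and PR2 at -1.39 (SE 0.16). Clock genes fell in 7 of 21 cases (7 lower and 1 higher over the list alone, camera adjusted p = 0.000102). CCA1 stood at 92.5 ± 7.49 against 218 ± 8.46 CPM (log2 -1.24, SE 0.09) and LHY at log2 -1.23 (SE 0.12). Both lists had an adjusted p = 0.778 with an estimated correlation. Jasmonate genes fell in 6 of 21 cases (8 over the list alone, camera adjusted p = 0.0325), with AOC2 at log2 -0.47 (SE 0.10), a gene nearly identical to AOC1. Photosynthesis genes were called higher as a list (2 of 48, 1 over the list alone, camera adjusted p = 0.00262), as were cell division markers (2 of 17, 4 over the list alone, 0.014) and heat shock genes (3 of 14, 3 over the list alone, 0.0377). HSP70 stood at log2 0.77 (SE 0.15) and AT2G29500 at 1.76 (SE 0.30). With an estimated correlation the adjusted p of these 4 lists was 0.778 to 0.945. The high-light genes ELIP1 and ELIP2 rose by log2 1.33 (SE 0.17) and 1.41 (SE 0.21), BAM5, a beta-amylase gene, had a log2 of -1.15 (SE 0.15), and CYP79B2 of -0.65 (SE 0.09). The edgeR calls came to 1643 of 20495 genes, 921 higher and 722 lower, and to 1082 without wild-type replicate 2, 930 without hda6 replicate 1 and 977 without hda6 replicate 3. Without wild-type replicate 1 they rose to 2125, and a replicate block raised them too, as given below. AOC1 lost its call without wild-type replicate 3 (adjusted p = 0.0523), and with all 30 libraries in one model PR2, AOC2, AOC1, BAM5 and AT4G10500 were not called (adjusted p = 0.0665, 0.15, 0.445, 0.141 and 0.225). Among the lists, photosynthesis lost the camera call without wild-type replicate 2 (adjusted p = 0.308) and cell division without wild-type replicate 2 (0.096) or hda6 replicate 3 (0.0891). Jasmonate lost it without wild-type replicate 2 or 3 or hda6 replicate 1 or 3 (0.0552, 0.0703, 0.0712 and 0.203), and heat shock without wild-type replicate 1 or 2 or hda6 replicate 1 or 3 (0.131, 0.0552, 0.074 and 0.0742). Stem secondary wall genes were called lower without hda6 replicate 3 (0.0057). By fry the photosynthesis, salicylic acid, jasmonate, heat shock, abscisic acid and cell division lists were not called (adjusted p 0.156 to 0.379).

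The hda6 effect differed between day lengths for 5658 of 21913 genes in edgeR's interaction test, 2837 more positive and 2821 more negative at 16 h. Cell division markers were more positive at 16 h in 16 of 17 cases, glucosinolate genes in 18 of 27 (3 more negative), photosynthesis genes in 14 of 48, DNA methylation genes in 12 of 32 (1 more negative) and starch genes in 11 of 30 (2 more negative). More negative at 16 h were 9 of 14 senescence genes, 8 of 17 mitochondrial dysfunction genes, 11 of 23 jasmonate genes, 9 of 29 abscisic acid genes, 7 of 19 salicylic acid genes and 8 of 19 reactive oxygen genes (1 more positive). SAG12, a senescence protease gene, was higher by log2 7.87 in hda6 at 12 h and did not pass at 16 h (log2 -1.05, difference -8.91, SE 1.83, adjusted p = 0.00444). The SAG12 difference was -12.21 without 12 h wild-type replicate 2 and -12.65 without 16 h hda6 replicate 2. DMP1, overlapped on the other strand to a part of 0.339, differed by -5.49 (SE 0.92, adjusted p = 0.00155). The noncoding AT4G07250 had 1 count in wild type and 662 in hda6 at 12 h, 3 and 0 at 16 h, and its difference (adjusted p = 0.00424) was lost without 16 h wild-type replicate 1 (adjusted p = 1). Here too the 2 day lengths were measured in different sets.

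In the libraries labelled sal1, jasmonate genes were higher in 21 of 23 cases, lower in 1 and not called in 1, also over the list alone (camera adjusted p = 3.45e-06, adjusted p = 0.556 with an estimated correlation). Over all 21845 tested genes edgeR called 5454 higher and 4656 lower, against which the list counts are to be read. The lipoxygenase gene LOX4 stood at 115 ± 27.8 against 26.2 ± 1.18 CPM (log2 2.13, SE 0.17) and JAZ5 at log2 2.67 (SE 0.27). Flavonoid genes were higher in 16 of 19 cases (16 over the list alone, camera adjusted p = 0.000246, adjusted p = 0.556 with an estimated correlation). The anthocyanin regulator MYB75 stood at 46.6 ± 10.6 against 8.39 ± 2.48 CPM. Glucosinolate genes rose in 20 of 27 cases and fell in 3 (22 and 3 over the list alone, camera adjusted p = 0.000511). CYP79B2 stood at 581 ± 228 against 103 ± 8.79 CPM and CYP79F2 at log2 2.28 (SE 0.18). Mitochondrial dysfunction genes rose in 13 of 16 cases and fell in 1 (14 and 1 over the list alone, camera adjusted p = 0.000511). The alternative oxidase gene AOX1A stood at 111 ± 20.9 against 31 ± 4.26 CPM. With an estimated correlation these 2 lists had an adjusted p of 0.566 and 0.556. Sulfate assimilation genes rose in 10 of 15 cases (10 over the list alone, camera adjusted p = 0.00216), with APR1 at 473 ± 56.7 against 160 ± 29.9 CPM. Abscisic acid genes rose in 15 of 29 cases with 2 lower (15 and 2 over the list alone, camera adjusted p = 0.00803), with HAI2 at log2 1.90 (SE 0.17). Shikimate genes rose in 13 of 25 cases with 2 lower (13 and 2 over the list alone, camera adjusted p = 0.0288), with TSB2 at log2 1.33 (SE 0.17). Senescence genes rose in 9 of 14 cases (9 over the list alone, camera adjusted p = 0.0312), with PPH at log2 1.22 (SE 0.19). The adjusted p of these 4 lists with an estimated correlation was 0.556 to 0.601. Without wild-type replicate 1 the shikimate and senescence lists lost the camera call (adjusted p 0.0539 and 0.0683). Cell division markers fell beside these groups (12 of 17), and these libraries differed from wild type in their share of ambiguous entries, 0.445% ± 0.0165 against 0.25% ± 0.0122.

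Lower in the libraries labelled sal1 were cell division markers in 12 of 17 cases (15 over the list alone, camera adjusted p = 0.000278). TSO2 stood at 26.1 ± 7.33 against 108 ± 14.9 CPM. Photosynthesis genes fell in 13 of 48 cases (8 over the list alone, camera adjusted p = 0.000511), with RBCS1A at log2 -1.27 (SE 0.26). That count stands beside 4656 of all 21845 tested genes called lower. DNA methylation genes fell in 13 of 31 cases with 3 higher (13 and 3 over the list alone, camera adjusted p = 0.00841). ROS1 stood at 22.9 ± 1.64 against 89 ± 6.87 CPM. Their adjusted p with an estimated correlation was 0.556, 0.618 and 0.556. Reactive oxygen genes rose in 11 of 19 cases and fell in 2 (camera adjusted p = 0.0764, but 0.0425 with a replicate block and 0.0399 without replicate 1 of the libraries labelled sal1). APX2, an ascorbate peroxidase gene, had a count ratio of 324 (95% counting interval 89.5 to 2680), and floral PISTILLATA (PI) of 51.1 (8.85 to 2050) in a floral organ list with 3 of 4 members higher (camera adjusted p = 0.0541). The floral list was called higher with a replicate block (0.0464), without wild-type replicate 2 (0.037) and without replicate 2 of the libraries labelled sal1 (0.0347). Heat shock genes rose in 9 of 16 cases and fell in 2 (9 and 2 over the list alone, camera adjusted p = 0.0501, 0.556 with an estimated correlation), and were called with the block (0.0425), without wild-type replicate 2 (0.0314) or 3 (0.0296), and without replicate 1 (0.0413) or 3 (0.019) of these libraries. Salicylic acid genes were called lower without wild-type replicate 1 (0.00807), and stem secondary wall genes without wild-type replicate 3 (0.013). By fry the photosynthesis and senescence lists were not called (adjusted p = 0.212 and 0.0666), and the reactive oxygen, floral and heat shock (0.0108 each), flowering (0.0397) and clock lists (0.0194) were. The 6 genes ranked highest by fitted fold change were near silence in wild type, so their rank rests on few or 0 wild-type counts: AT5G35640, AT1G48405, AT2G14755, AT2G20970 and AT2G16586 had 0 wild-type counts and were at least 267-, 266-, 256-, 256- and 243-fold higher, and AT1G64795, overlapped to a part of 0.707, had a count ratio of 3170 (569 to 125000). MRD1 (overlap 0.898) and AT3G46490 both had a log2 of -4.61 (SE 0.26 and 0.45). The acyltransferase gene AACT1 had a log2 of -4.61 (SE 0.87) and BHLH100, a regulator of iron uptake, of -3.97 (SE 0.70). GASA6 and AT1G74675, overlapped to a part of 0.226 and 0.17, had log2 values of -3.99 (SE 0.20) and -4.23 (SE 0.23). Without wild-type replicate 1 the log2 of AACT1 was -3.31, and without replicate 1 of the libraries labelled sal1 those of BHLH100 and AT3G46490 were -5.23 and -5.26. Ratios on a few wild-type counts, for APX2, PI and AT1G64795, also moved by over 1.5-fold when 1 library was left out. CCA1 was higher (log2 1.46, SE 0.21) and the clock list had 3 members higher and 8 lower of 21. edgeR called 10110 of 21845 genes, 5454 higher and 4656 lower in the libraries labelled sal1, 4021 of them at least 2-fold (2967 higher). Of the 2967, 1035 were nuclear genes below 0.5 CPM in wild type. Such genes passed the filter mostly through their counts in the libraries labelled sal1, and are taken up again below.

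The libraries labelled msh1 had lower jasmonate, glucosinolate and abscisic acid genes. Over all 20785 tested genes edgeR called 3609 higher and 3327 lower. Jasmonate genes fell in 20 of 22 cases (20 over the list alone, camera adjusted p = 1.47e-12). The storage protein gene VSP2 stood at 25.5 ± 11.4 against 245 ± 10.8 CPM and the repressor JAZ9 at log2 -2.25 (SE 0.18). Abscisic acid genes fell in 22 of 29 cases (24 over the list alone, camera adjusted p = 7.12e-12), with RD20 at 5.68 ± 0.291 against 58.2 ± 13.8 CPM. Both had an adjusted p = 0.243 with an estimated correlation. Glucosinolate genes fell in 24 of 27 cases (24 lower and 1 higher over the list alone, camera adjusted p = 2.24e-12, adjusted p = 0.259 with an estimated correlation). CYP79B3 stood at 53.5 ± 8.87 against 169 ± 9.2 CPM. Phenylpropanoid genes fell in 13 of 17 (15 over the list alone, camera adjusted p = 1.1e-06, adjusted p = 0.243 with an estimated correlation), with CAD5 at log2 -1.22 (SE 0.09). Photosynthesis genes fell in 20 of 48 with 1 higher (25 and 1 over the list alone, camera adjusted p = 1.1e-06, adjusted p = 0.599 with an estimated correlation). LHCB2.2 stood at 942 ± 173 against 3132 ± 314 CPM. Shikimate genes (15 lower and 2 higher of 25, 16 and 2 over the list alone, camera adjusted p = 0.000338) and flavonoid genes (7 lower of 19, 10 lower and 1 higher over the list alone, 0.000507) were also called lower. So were starch genes (14 lower and 4 higher of 30, 16 and 5 over the list alone, 0.0112), heat shock genes (6 lower of 14, 6 over the list alone, 0.0463) and salicylic acid genes (6 lower and 1 higher of 19, 7 and 1 over the list alone, 0.0186). Their adjusted p with an estimated correlation was 0.432, and 0.654 for the salicylic acid genes. The salicylic acid list lost the camera call without wild-type replicate 1 (adjusted p = 0.0604), and the heat shock list without wild-type replicate 3 (0.0528) or replicate 2 or 3 of the libraries labelled msh1 (0.0552 and 0.0846), and with RLE factors (0.0501). By fry the salicylic acid list was not called (adjusted p = 0.2). In these lists TSB2 had a log2 of -1.09 (SE 0.11), UGT78D1 of -1.09 (SE 0.11), GBSS1 of -3.62 (SE 0.21), HSP70 of -1.87 (SE 0.19) and PR2 of -2.49 (SE 0.38).

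Higher in the libraries labelled msh1 were cell division markers in 13 of 17 cases (13 over the list alone, camera adjusted p = 2.83e-06, adjusted p = 0.341 with an estimated correlation). MCM7 stood at 40.1 ± 3.69 against 22.9 ± 3.03 CPM. Floral organ markers rose in 7 of 10 cases (9 over the list alone, camera adjusted p = 0.000507, adjusted p = 0.259 with an estimated correlation), with SEP3 at 2.82 ± 0.353 against 0.247 ± 0.123 CPM and CRC at a count ratio of 12.6 (95% counting interval 4.03 to 63.9). These markers of dividing and floral tissue moved beside every group named for these libraries. DNA methylation and deacetylation genes rose in 14 of 32 cases and fell in 1 (14 and 1 over the list alone, camera adjusted p = 0.000507, adjusted p = 0.243 with an estimated correlation), with the deacetylase genes HDT1 and HDT2 at log2 1.401 (SE 0.11) and 0.81 (SE 0.10), which are overlapped to a part of 0.222 and 0.17. Among mitochondrial dysfunction genes 8 of 17 rose and 2 fell (camera adjusted p = 0.154): AT12CYS-2 stood at 16.5 ± 9.12 against 0.115 ± 0.148 CPM, the alternative NADH dehydrogenase gene NDB4 at log2 5.89 (SE 0.85) and UPOX at 2.26 (SE 0.26). BT2 rose to 62.3 ± 8 from 2.19 ± 1.89 CPM, AT2G04050 by log2 4.61 (SE 0.91), AT5G52940 by 4.08 (SE 0.38), and MEE48 had a count ratio of 326 (58.2 to 12900). MAF5 stood at 0.0993 ± 0.0467 against 26.2 ± 3.85 CPM (log2 -7.94, SE 0.27), the stress regulator RAP2.6 at a count ratio of 0.00353 (0.000427 to 0.0128), AT1G75945 at 0.00315 (7.95e-05 to 0.0177), and CYP94B3, RD29B and TPS10 at log2 -5.83 (SE 0.77), -5.50 (SE 0.88) and -5.32 (SE 0.67). Without replicate 2 of the libraries labelled msh1 CYP94B3 and TPS10 had log2 values of -7.79 and -6.42, without replicate 3 of these NDB4 had 5.29, and without wild-type replicate 3 BT2 had 5.81 and AT12CYS-2 8.89. The count ratios of RAP2.6, AT1G75945, MEE48 and CRC also moved by over 1.5-fold when 1 library was left out. The clock list had 9 members higher and 11 lower of 21, with LNK3 at log2 -3.89 (SE 0.12), CCA1 at -5.09 (SE 0.19) and FKF1 at 2.90 (SE 0.10). By fry the clock (adjusted p = 0.0024) and mitochondrial lists (0.0263) were called. edgeR called 6936 of 20785 genes, 3609 higher and 3327 lower.

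**Figure D3:**
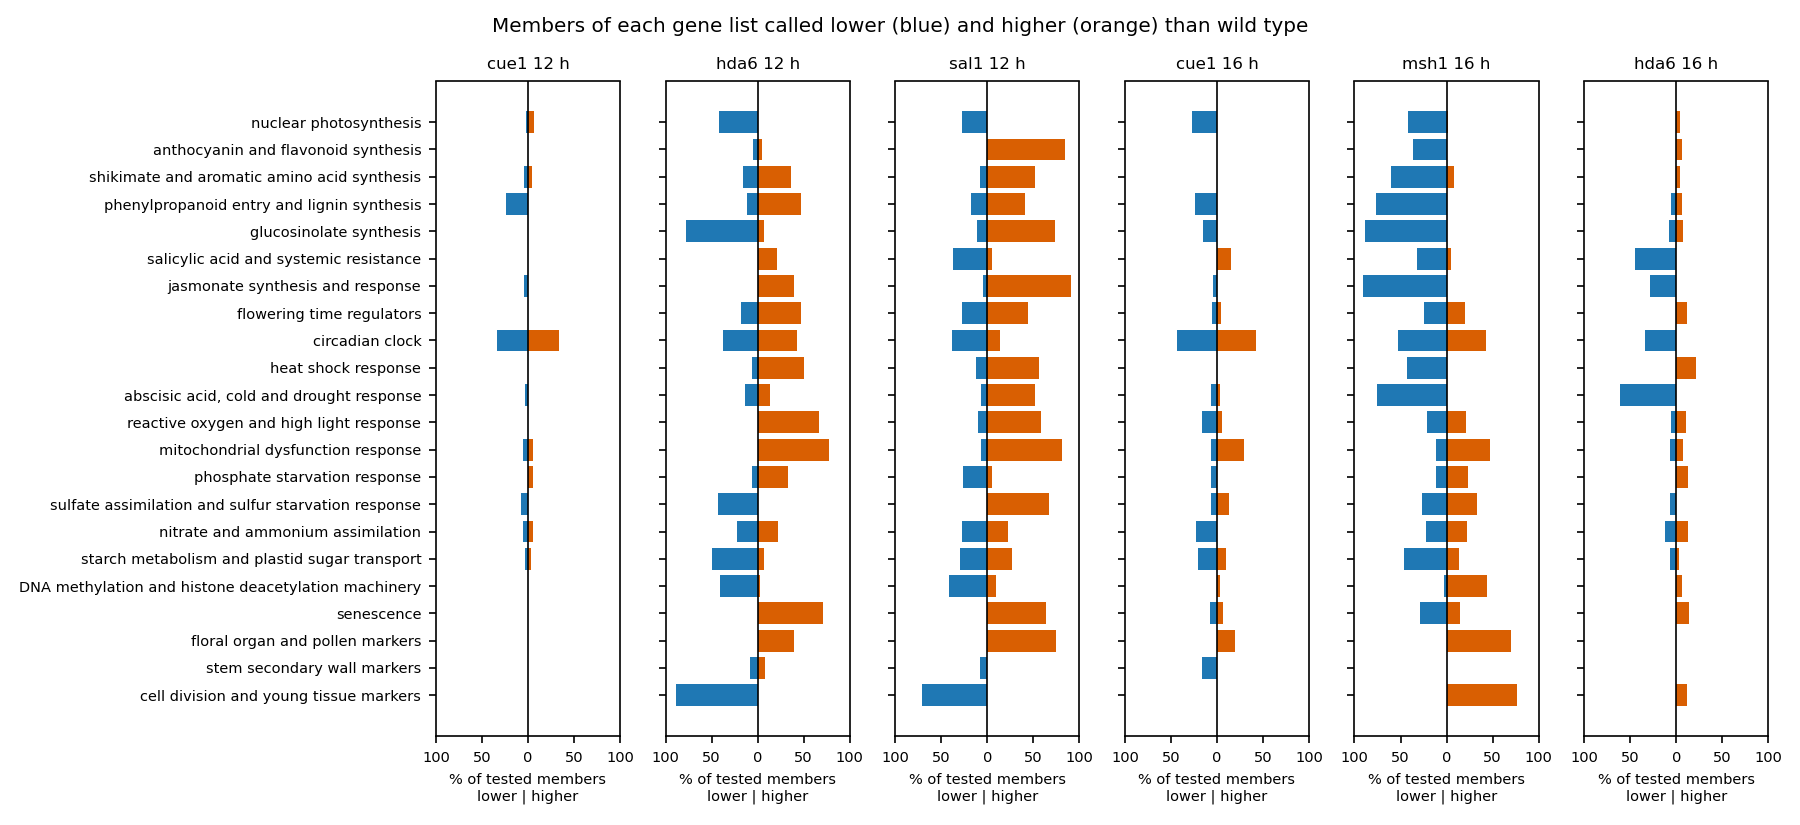
Percentage of the tested members of each of 22 gene lists called lower (blue, to the left) and higher (orange, to the right) than wild type by edgeR at an adjusted p under 0.05, in 6 comparisons (n = 3 libraries per group). Jasmonate genes are higher in 21 of 23 cases in the libraries labelled sal1 and lower in 20 of 22 in those labelled msh1.

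The comparisons were then set against each other, to ask which changes cue1 and the libraries labelled sal1 and msh1 share with hda6 and with each other. At 12 h, cue1 and hda6 shared 163 calls in the same direction and 53 in opposite directions, with AT3G01345, AT3G04650 and JMJD5 higher in both and LHY, CCA1 and COL2 lower in both. Independent lists would share 60.4 higher and 21.9 lower genes, against 109 (Fisher's exact p = 2.6e-11) and 54 (Fisher's exact p = 7.51e-12). The log2 odds ratio was 1.47 (SE 0.15), but 2.94, 2.13 and 2.44 without wild-type replicates 1, 2 and 3, 2.91, 2.33 and 2.71 without cue1 replicates 1, 2 and 3, and 2.13 without hda6 replicate 2. Fold changes correlated across genes at r = 0.27, while 20 simulations of unchanged groups against the shared wild type gave r = 0.5 on average. The covariance was 0.135 against a simulated 0.0339, a difference of 0.101. At 16 h, cue1 and the libraries labelled msh1 shared 535 higher and 590 lower genes, where independent lists would share 121 and 114, and 15 genes went in opposite directions (log2 odds ratio 4.55, SE 0.10). That ratio was 5.24, 5.77 and 5.59 without wild-type replicates 1, 2 and 3, and 3.72, 3.74 and 5.57 without cue1 replicates 1, 2 and 3. The shared genes included AT2G04050, AT1G07050 and AT4G33980 among the higher and MAF5, LHY and CCA1 among the lower. Here r was 0.591 (simulated 0.506) and the covariance 0.21 (simulated 0.027, difference 0.183). The 3 shared wild-type libraries cannot be divided into parts of at least 2, so part of either excess may come from these shared controls.

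Other pairs had separate wild types. The next 2 pairs were chosen after the data were seen, span both day lengths and were not rerun under the alternatives. Cue1 at 12 h and the libraries labelled msh1 shared 249 calls in the same direction (65 for independent lists) and 4 in opposite directions (log2 odds ratio 3.12, SE 0.17). The libraries labelled sal1 and msh1 shared 673 and 3161, against 1520 of each (log2 odds ratio -1.56, SE 0.06). The libraries labelled sal1 and hda6 at 12 h shared 3079 calls in the same direction and 961 in opposite directions (log2 odds ratio 1.39, SE 0.04), among them higher DIN2 and BRU6 and lower XTH7 and AT2G10940. The libraries labelled msh1 shared 472 calls with hda6 at 16 h, with 159 in opposite directions (log2 odds ratio 1.34, SE 0.08), among them higher MES18 and AT1G23410 and lower COR15A, PUB19 and AT4G10500. For cue1 and hda6 at 16 h the shared calls numbered 96 and the opposite ones 91, where independent lists would give 49.5 of each, so calls coincided without a common direction (log2 odds ratio of the shared calls 1.11, SE 0.16, rank correlation -0.0251). That ratio was 0.71 and 1.75 without replicates 1 and 2 of the wild type for hda6, 1.76 without hda6 replicate 3, 1.70 without replicate 2 of the wild type for cue1 and 1.69 without cue1 replicate 3. Calls in cue1 and in the libraries labelled sal1 at 12 h went in opposite directions in 180 genes and in the same direction in 54 (log2 odds ratio -0.73, SE 0.21). That value was 0.28 without cue1 replicate 1 and 0.03 without wild-type replicate 3 of the cue1 set, and the test of the ratio no longer passed without wild-type replicate 1 of that set (-0.35), cue1 replicate 2 (-0.06) or 3 (-0.65), or replicate 2 of the libraries labelled sal1 (-0.35). It was -0.43 without replicate 3 of the wild type for sal1. This value for cue1 and the libraries labelled sal1 was 1.84 for calls of at least 2-fold. Between day lengths, cue1 shared 107 calls in the same direction and 2 in opposite directions (log2 odds ratio 3.74, SE 0.18), with AT3G01345, AT3G04650 and JMJD5 higher and CUE1, LHY and MRD1 lower in both. Without 12 h wild-type replicates 1 and 3 that ratio was 4.82 and 4.51, without 12 h cue1 replicates 1, 2 and 3 it was 5.05, 4.34 and 4.59, and without 16 h wild-type replicate 2 and cue1 replicate 3 it was 4.62 and 4.69. For hda6, 452 genes were higher at both day lengths against 177 for independent lists (Fisher's exact p = 2.06e-101), whereas 152 were lower against 147 (Fisher's exact p = 0.672) and 291 went in opposite directions. AT2G15555, AT5G15360 and AT3G60950 were higher, and AT4G34220, PORA and AT3G27870 lower, at both day lengths.

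Wild types of the 16 h sets differed from those of the 12 h sets. Taking genes called in the same direction in all 4 pairs of a 16 h and a 12 h wild-type set, 1012 of 21044 were higher and 992 lower at 16 h. These 4 pairs reuse the same 4 sets, and no other grouping of whole sets was counted. Sets of one day length differed as well, in 7873 genes at 12 h and 4280 at 16 h. Day length and set therefore cannot be told apart here. Clock genes were higher at 16 h in 8 of 21 cases (CCA1, LHY, PRR9, RVE1, RVE4, RVE8, LNK2 and LNK3) and lower in 7 (TOC1, PRR3, GI, ELF3, ELF4, LUX and FKF1). Wild types of one day length also differed in these genes. Between the 12 h sets 16 of 21 clock genes were called, with PRR9 at log2 -2.12 and CCA1 at -1.67 in the set with sal1. Between the 16 h sets 17 of 21 were called, with FKF1 at log2 -4.36, PRR3 at -3.43 and LHY at 1.46 in the set with hda6. Photosynthesis genes were higher at 16 h in 15 of 48 cases, phenylpropanoid genes in 8 of 17 and nitrate assimilation genes in 4 of 18, and the flowering activators FT and SOC1 were higher. Lower at 16 h were COR27, a cold-regulated gene, by log2 -9.43 to -3.55 over the 4 pairs, AT1G07050 by -7.45 to -3.17 and AT4G33980 by -6.94 to -3.59. AT4G08815 was higher by 2.75 to 8.32, AT3G16670 by 2.71 to 4.46 and AT4G08295 by 2.71 to 4.99. Sampling at another hour of the day would also change clock genes, and no label used here gives the hour.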

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

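The tests on day length and on quartiles of the neighbour for the opposite-strand pattern, on chance values of the shared wild-type libraries, on another hour of harvest and on 3′ ends against every near-silent gene were chosen after the results they explain had been seen. The other tests of this part were written before.

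The effects of cue1 and of hda6 differed between day lengths by the interaction test. For cue1 168 genes differed, with AT3G06955 (3.84), AT1G07050 (2.48) and FKF1 (2.201) more positive at 16 h, and MAF5 (-7.00), AT3G02370 (-2.26) and AT4G33666 (-2.01), overlapped on the other strand to a part of 0.127 and 0.482, more negative, as differences of log2 fold changes. For hda6 5658 genes differed, with AT4G22475 (10.44), AT4G22485 (10.19) and AT4G22495 (8.81) more positive and AT4G07250 (-12.29), SAG12 (-8.91) and DMP1 (-5.49) more negative. AT4G22475, AT4G22485 and AT4G22495 are overlapped on the other strand to a part of 0.815, 0.935 and 0.989 and DMP1 to 0.339, so they are uncertain. The values of the AT4G22475 group and AT4G07250 rest on groups with few counts and are no bounds. When genotype labels were exchanged within each day length, 3 of 100 drawn splits called at least 168 genes for cue1, the real one included, with 340 in the highest other, and 1 of 100 reached 5658 for hda6, with 5128 in the highest other. These splits take out the genotype effect as well as its difference, so for both interactions chance stays open. For wild type and day length 1 of 100 splits reached 2004 genes, with 0 in the highest other, but dealing single libraries breaks up the sets, which differ at one day length too, so chance stays open here as well.

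For 3 against 3 libraries there are 10 splits, so the share is never under 0.1, and 1 of 10 gave as many genes in each case. The real counts and the highest of the other splits were 381 and 2 for cue1 at 12 h, 8675 and 1 for hda6 at 12 h, 10110 and 0 for the libraries labelled sal1, 1404 and 6 for cue1 at 16 h, 6936 and 1 for the libraries labelled msh1, and 1643 and 0 for hda6 at 16 h. Between wild types they were 7873 and 0 at 12 h and 4280 and 0 at 16 h.

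Of 12 shares of entries that the files assign to no gene, 6 differed between mutant and wild type without overlap of the 3 and 3 libraries, which an exact permutation test gives as p = 0.1, the smallest possible, and the other 6 overlapped (p = 0.2 to 1). The share of ambiguous entries was 0.279% ± 0.0057 in hda6 at 12 h (wild type 0.259% ± 0.0132) and 0.445% ± 0.0165 in the libraries labelled sal1 (wild type 0.25% ± 0.0122). The share without a feature was 49.2% in the libraries labelled sal1 (wild type 48.6%), 48.3% in cue1 and 48.4% in the libraries labelled msh1 at 16 h (wild type 48.1%), and 49.5% in hda6 at 16 h (wild type 49.3%).

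Genes overlapped on the other strand were counted higher in 3 sets than in the 12 h set with cue1 and hda6. In 563 genes covered by a neighbour to at least 90%, the median log2 ratio of their read density to that of the neighbour was -4.36 in the wild type of that set and 0.361 at the lowest in the 3 others, in line with counts that do not tell the strands apart in those sets. Day length is argued against, since the 12 h wild types differ by a median log2 of 3.97 in these genes. Genomic DNA, which adds one density to every gene, is argued against by a median density of covered genes higher by a log2 of at least 3.51 (2.91 to 4.04) in the highest than in the lowest quartile of the neighbour's density, and by 54.5% to 56% of 23907 genes without overlap lying below 0.25 of the covered median, although the lowest rank correlation of both densities, 0.515 (0.43 to 0.593), decides nothing alone. The same 3 sets had 48% to 49.6% of entries assigned to no gene, against 2.58% to 5.78% in the other set. Ambiguous entries were at 0.207% to 0.458% in the 3 sets and at 0.241% to 0.286% in the other. Whether the libraries or the strand setting of the counting differed between sets was not tested. No biological explanation was tested.

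Calls shared by cue1 and the libraries labelled msh1 at 16 h numbered 1125 in the same direction. Chance values of the shared wild type are argued against by a covariance of 0.21, with 0.0281 as the highest of 20 simulations. These simulated unchanged groups, so they do not cover a shift common to the shared wild-type libraries. The other 16 h wild type had a slope of -0.123 (-0.153 to -0.0908) on the shared changes. It lay on the mutants' side in 31.2% of these genes, with 100 called on that side and 365 on the other. That wild type is of another set and differs from the shared one in 4280 of 21044 genes. The slope therefore cannot decide whether the shared wild-type libraries stand apart. Another hour of harvest cannot be told apart from an effect of the genotypes: 18 clock genes moved alike in both comparisons, and no label gives the hour. A change in the plastid shared by cue1 and the libraries labelled msh1 stays open as well, as untested.

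Genes near silence in wild type were higher in the libraries labelled sal1, with 1035 called at least 2-fold higher by edgeR. Library size is argued against, since after thinning every library to 15632452 counts the lowest of these libraries still detected 1212 more genes than the highest wild-type library. Reads of a gene on the other strand are argued against as the whole source, since 70.2% of these genes have no such overlap. They lay within 1 kb of the 3′ end of an expressed gene in 66.6% of cases against 16.6% of the 10743 other near-silent nuclear genes (odds ratio 9.98, 8.67 to 11.5), and near a 5′ end in 17.9% against 17.3%, while the odds ratio of 6.01 against tested genes not called decides nothing, since the filter selects those genes by their counts. Reads that run past the 3′ end of expressed neighbours may therefore be a source, as a hypothesis tested on the same data.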

How the results depend on the processing

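Fits without opposite-strand genes and without the 2 libraries that stood apart were chosen after the data were seen. The cause was not tested for any change below, except that stricter thresholds call fewer genes by construction.

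With an adjusted p under 0.05 and a log2 of at least 1, and with an adjusted p under 0.01, the counts were 91 and 31 for cue1 at 12 h, 2778 and 4836 for hda6 at 12 h, 4021 and 6269 for the libraries labelled sal1, 312 and 468 for cue1 at 16 h, 1639 and 4192 for the libraries labelled msh1, and 605 and 806 for hda6 at 16 h. They were 62 and 34 for cue1 by day length, 2193 and 2504 for hda6 by day length, 2744 and 5245 between the 12 h wild types, 1052 and 2103 between the 16 h wild types, and 328 and 964 for day length.

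DESeq2 called 1184 genes for cue1 at 12 h and 925 for cue1 by day length. With all 30 libraries in one model these counts were 656 and 558. With only the groups compared, cue1 gave 166 at 12 h and 921 at 16 h. A replicate block gave 168 for cue1 at 12 h and 2743 for hda6 at 16 h. Without the 2 libraries that stood apart, cue1 at 12 h gave 50. The remaining counts stayed within 1.5 times under DESeq2, RLE factors, nuclear scaling (which moves nothing, since the organelle genes are at 0), no filter, a stricter filter, the block, all libraries, only the groups compared, and without opposite-strand genes.

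The overlap of cue1 and the libraries labelled sal1 at 12 h (log2 odds ratio -0.73) turned to 1.84 with a log2 of at least 1, 0.96 with an adjusted p under 0.01, 0.046 with a replicate block, 0.03 without 12 h wild-type replicate 3 and 0.28 without cue1 replicate 1. It was -0.13 without the 2 libraries that stood apart, and ran from -0.97 to 0.28 with 1 library left out. The other 7 planned overlaps kept their direction and their side of the threshold under every alternative run.

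With 1 library left out, counts ran from 32 to 303 for cue1 at 12 h, 6134 to 8374 for hda6 at 12 h, 8089 to 10221 for the libraries labelled sal1, 563 to 1685 for cue1 at 16 h, 5078 to 6903 for the libraries labelled msh1, 930 to 2125 for hda6 at 16 h, 47 to 369 for cue1 by day length, 3900 to 6061 for hda6 by day length, 6039 to 7478 and 2845 to 3970 between wild types at 12 h and 16 h, and 1391 to 2169 for day length. The low of 2845 came without 16 h wild-type replicate 2. List tests called by camera ran from 56 to 64 of 132, and 0 of the 60 were called with an estimated correlation (9 at an unadjusted p under 0.05, fry 46).

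Of 318 named gene results 243 kept their call and direction under every alternative run on them, and 75 changed under some alternative. Of 5425 values 0 were reversed and 216 weaker. This counts calls and directions, not the size of fold changes, and some alternatives covered only part of the results. Of 132 list results 0 reversed, and among their alternatives 107 values became weaker and 42 stronger. Between sets, depth ran from 14417942 to 33747006 gene counts per library, which limits calls for genes with few counts.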

Other observations

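Of 19160 genes tested in all 6 mutant comparisons, 8 were called in one direction in all of them. Higher were AT3G04650 (log2 1.86 to 3.41, largest adjusted p = 0.000221 in edgeR) and AT3G57770 (0.794 to 1.958), which a gene on the other strand overlaps in part. Lower were RVE8, LNK3 (AT3G12320), AT4G15430, BBX28, AT5G06980 and RVE1. In the 5 comparisons other than the libraries labelled sal1, 17 genes were called in one direction, 2 higher and 15 lower. These genes were chosen after their values were seen, and pairs of these comparisons share a wild type.

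MAF5 varied among the wild types, at 3.59 ± 2.9 and 18.8 ± 6.32 CPM in the 12 h sets with cue1 and with sal1, and at 26.2 ± 3.85 and 1.04 ± 0.489 CPM in the 16 h sets with cue1 and with hda6. The MAF5 differences between mutants and wild type, given for each set, start from these levels. In cue1 at 16 h MAF5 was at 0.761 ± 0.196 CPM, near the 16 h wild type of the hda6 set. In the libraries labelled msh1 it was at 0.0993 ± 0.0467 CPM.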
